A study of Homo sapiens with 4 samples.

How the data were processed

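RNA-seq and small RNA sequencing (miRNA-seq) were each run on 1 library of H1975 cells kept for 24 h in normoxia and 1 library kept for 24 h in hypoxia, 4 libraries in all. Per the labels' protocols, RNA was taken with TRIzol for libraries made with a stranded mRNA kit, and total RNA was taken with the mirVana kit for small RNA libraries. The submitters' processing notes name Trimmomatic, HISAT2, Cufflinks, HTSeq and Bowtie and the genome build GRCh38, without versions or roles. Whether the counting used strand is not given in the sources used here.

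The RNA-seq values used were the read counts per gene that the authors deposited, whole numbers for 15562 genes. The authors also deposited FPKM for the same genes, and these equalled the counts divided by the library's table total and a gene length: the log2 ratio from FPKM differed from that of the counts by -0.10 for every gene, and the implied lengths were whole within 0.01 bases for 100% of genes with a count. The FPKM therefore carry no scaling beyond the total. The miRNA-seq values used were the read counts per mature miRNA that the authors deposited, for 141 miRNAs. The TPM that the authors deposited equalled these counts times 1 constant per library, with no length term. The constants imply totals of 8889769 reads in normoxia and 10936385 in hypoxia, and what those totals hold is not given in the sources used here.

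Total counts were 17643836 in the normoxia and 18943320 in the hypoxia RNA-seq library, and 32116 and 6576 in the miRNA-seq libraries. At these depths 1 read equals a scaled CPM of 0.0565 and 0.0530 in RNA-seq, and of 35.9 and 132 in miRNA-seq. A count of 0 was taken to allow up to 3 counts in that library. All intervals and floors cover counting error only. Reads without molecular identifiers are not independent molecules, so the true error is larger.

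Counts were scaled with the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3. Ratios, intervals and lists were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The ratio of hypoxia to normoxia was given with its exact conditional (Clopper-Pearson) 95% counting interval. Genes at a CPM of 1 or more and miRNAs at a CPM of 10 or more in at least 1 library were kept. The miRNA filter removed nothing, because 1 read already lies above it. A gene or miRNA was called higher or lower in hypoxia by size, when its ratio was 2 or more either way and its interval excluded 1. With 1 library per group there is no spread between replicates, so no p-value for the condition was computed, and a call describes 2 libraries.

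The lists of 38 gene groups and 15 miRNA groups, the rule for the genes named and the settings to be varied were fixed before the data were examined. Named genes were the 12 highest and 12 lowest by the interval bound nearest to no change, the extreme members of each list, and a fixed set that holds KLF2, KDR, VEGFA, HIF1A, EPAS1, ARNT, CA9, EGFR and CHPF2. For miRNAs the rule took 8 in each direction, the extreme members of each list and a fixed set. The set was miR-671-3p, miR-671-5p, miR-210-3p, miR-210-5p and miR-21-5p, of which only miR-671-3p and miR-21-5p were among the miRNAs with values. 1 Y-linked gene that the ranking reached was not named. Some genes that the rule reached are not reported here. The median log2 ratio of a list was set against 10000 random lists of the same size matched on mean expression, and its interval came from 2000 Poisson redraws of the counts. Of the genes, 15526 matched an Entrez identifier in a RefSeq table of GRCh38.p14, from which coordinates were taken.

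The procedure was tested on simulated data drawn from the real means and library sizes. For the RNA-seq comparison, with 12688 genes passing the filter, the size rule called 67 of 67 genes changed 2.5-fold, 66 of 66 changed 4-fold and 0 of 67 changed 1.5-fold in the right direction. It also called 26 of 12488 unchanged genes. For the miRNA-seq comparison, with 138 miRNAs, it called 7 of 7 changed 2.5-fold, 6 of 7 changed 4-fold and 6 of 6 changed 8-fold, and 0 of 118 unchanged. The intervals held the true ratio for 95.6% of genes and 97.8% of miRNAs. Of 100 unchanged lists of 30 genes, 2 lay above and 1 below the central 95% of matched lists, and 100 of 100 lists shifted by 0.2 log2 lay above it. The changed genes and miRNAs were drawn only from those with higher expression. Recovery of changed genes or miRNAs with few reads was therefore not tested. Most of the real RNA-seq calls lie among genes with few reads. The simulation holds counting error only.

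The other settings were DESeq2 1.42.0 size factors, total counts, upper quartile scaling for RNA-seq, the authors' FPKM with a pseudocount of 1 or 0.1, the authors' TPM with a pseudocount of 1 or 10, no filter, a filter at a CPM of 5 (RNA-seq) or 50 (miRNA-seq), and an interval wholly beyond a ratio of 1.5. With FPKM or TPM the ratio carried the pseudocount and the interval came from the counts. A search of 3 prime UTRs for seed sites of miR-671-3p had been planned and was not run, because no genome sequence was used here.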

Results

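H1975 is a human lung adenocarcinoma cell line. Cells were kept for 24 h in normoxia or in hypoxia (1% O2, 5% CO2, 94% N2), and each condition was measured by 1 RNA-seq and 1 miRNA-seq library. There are no replicates, so each difference is given with the interval that counting error allows, and none was tested against the spread between cultures. The RNA-seq libraries held 17643836 counts in normoxia and 18943320 in hypoxia. The miRNA-seq libraries held 32116 and 6576 reads on known miRNAs. The series title names exosomal miR-671-3p, KLF2 and VEGFR2. The labels of all 4 libraries describe H1975 cells, and the values are read as those of cells. The sources used here do not say how the miRNA libraries relate to the exosomes of the title.

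The first comparison asked which transcripts differed between hypoxia and normoxia. Genes that hypoxia-inducible factors (HIF) are known to activate were higher in hypoxia. NDRG1, a stress-responsive gene, had 5214 counts in hypoxia and 1958 in normoxia, a log2 ratio of 1.32 (95% counting interval 1.25 to 1.40). DDIT4, an inhibitor of mTORC1 signalling, had a ratio of 1.80 (1.69 to 1.92). VEGFA, the main angiogenic growth factor, had 3808 and 2268 counts, a ratio of 1.57 (1.49 to 1.66), and the carbonic anhydrase CA9 had a ratio of 1.43 (1.30 to 1.57). Of the 42 measured HIF targets, 40 had a log2 ratio above 0 and the interval of 33 lay wholly above 0, while 1 (NDRG1) passed the size rule of a 2-fold difference. Their median log2 ratio was 0.32 (0.29 to 0.38), and 0 of 10000 random lists matched on expression had a median as high. The members with the lowest values were BHLHE41 at -0.66 (-1.49 to 0.15) and JMJD6 at -0.11 (-0.31 to 0.10).

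Genes of glycolysis and glucose uptake were also higher, with a median log2 ratio of 0.18 (0.14 to 0.21) over 23 genes, 21 of them above 0, and 0 of 10000 matched lists as high. The glucose transporter SLC2A1 had a log2 ratio of 0.71 (0.61 to 0.81) and the hexokinase HK2 of 0.67 (0.58 to 0.77). ALDOA was at -0.29 (-0.73 to 0.14) on 87 counts in hypoxia and 100 in normoxia, a count too low for this abundant enzyme, and is uncertain because the counting may have set aside reads of overlapping genes. BNIP3, which marks mitochondria for removal, was at 0.65 (0.56 to 0.75) and the HIF hydroxylase EGLN3 at 0.63 (0.53 to 0.73). Of the transcripts of the factors themselves, HIF1A had a ratio of 0.967 (0.938 to 0.998), EPAS1 a log2 ratio of -0.04 (-0.10 to 0.02) and ARNT one of 0.04 (-0.10 to 0.19), while ARNT2, another partner subunit, had 36 counts in hypoxia and 13 in normoxia, a log2 ratio of 1.38 (0.43 to 2.42) that passed the size rule. Genes of pH and carbonate handling had a median of 0.15 (0.07 to 0.19) over 8 genes, at percentile 99.8 of matched lists, with CA12 at 0.31 (0.22 to 0.40).

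**Figure D1:**
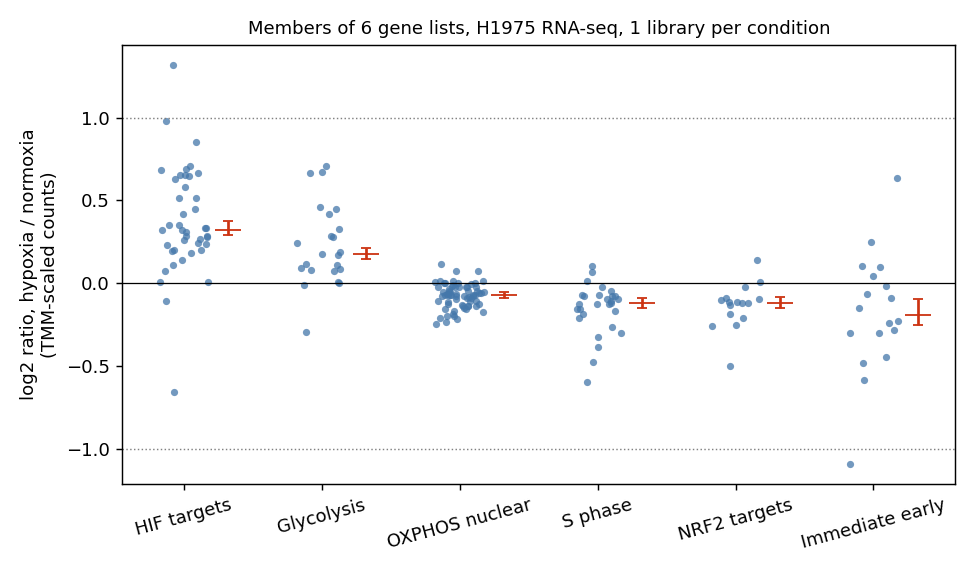
Each blue point is 1 gene of a fixed list, placed by its log2 ratio of hypoxia to normoxia in the RNA-seq libraries (y axis, log2 of TMM-scaled counts), and the red mark beside it is the list median with its 95% counting interval. The HIF targets centre on 0.32 and the glycolysis genes on 0.18, the S phase genes centre on -0.12, and dotted lines show a 2-fold difference.

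Several lists lay below 0 by small amounts. Of 28 S phase genes 25 were below 0, with a median of -0.12 (-0.15 to -0.09), and 0 of 10000 matched lists were as low. The cell cycle transcription factors E2F1 at -0.48 (-0.61 to -0.34) and E2F2 at -0.60 (-0.96 to -0.23) were lowest. Immediate early genes had a median of -0.19 (-0.25 to -0.09) over 18 genes, again with 0 of 10000 lists as low, although FOSB was at 0.64 (0.17 to 1.11) and JUNB at 0.25 (0.20 to 0.30). EGR2 was at -1.09 (-1.83 to -0.39) on 26 counts in hypoxia and 52 in normoxia. Targets of the oxidative stress factor NRF2 had a median of -0.12 (-0.15 to -0.08), with 14 of 16 below 0 and OSGIN1 lowest at -0.50 (-0.74 to -0.27). Nuclear genes of oxidative phosphorylation had a median of -0.07 (-0.09 to -0.05), with 59 of 68 below 0 and NDUFA12 at -0.25 (-0.42 to -0.08). The oxidative phosphorylation genes are short, and against lists matched on both expression and gene length their median lay at percentile 1.43. With the length trend removed (a step chosen after seeing the data) their median was -0.022. Cytosolic ribosomal proteins, also short, had a median of -0.04 (-0.05 to -0.03) over 74 genes, and with the length trend removed it was 0.0029.

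Replication-dependent histones were higher in hypoxia, with a median of 0.23 (0.13 to 0.33), 16 of 18 above 0, 2 called higher and a percentile of 99.9. The 2 calls rest on few counts: H1-3 had 27 in hypoxia and 8 in normoxia, and H2BC7 had 31 and 14. Mitotic (G2M) genes had a median of 0.05 (0.01 to 0.09) and interferon response genes 0.12 (0.01 to 0.15) at percentile 99.4. ATF4 targets were at 0.03 (-0.03 to 0.08), endoplasmic reticulum chaperones at 0.03 (0.00 to 0.06) and mesenchymal transition genes at 0.02 (-0.04 to 0.06). Angiogenic factors as a group had a median of -0.06 (-0.14 to 0.06), with 8 of 20 above 0: VEGFA and EFNA1 (0.37, 0.25 to 0.49) were the highest. Angiogenesis inhibitors were at -0.08 (-0.20 to -0.01) over 11 genes. Chromatin oxygenases that use oxygen and 2-oxoglutarate had a median of 0.13 (0.06 to 0.16) over 20 genes, at percentile 99.96 of matched lists. TET1 was highest at 0.42 (0.01 to 0.84) and RIOX1 lowest at -0.47 (-0.67 to -0.27). The chromatin oxygenase genes are long (median 8502 bases), and against lists matched on both expression and gene length their median lay at percentile 98.92. The median of each list not described otherwise lay between -0.06 (epithelial junction) and 0.06 (collagen modification), and mitochondrially encoded genes were not analysed here. Markers of other cell types were sparse. Of the 4 endothelial markers that passed the filter the median was -0.20 (-0.65 to 0.31), of 6 fibroblast markers 0.10 (-0.08 to 0.31) and of 4 leukocyte markers -0.45 (-0.69 to -0.16), the last at percentile 0.60 of matched lists and at 0.056 with a filter at a CPM of 5.

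By the size rule 60 genes were higher in hypoxia and 56 lower among 12725 that passed the filter, and most had few reads. The median log2 ratio of all genes was 0.00, and 96.4% of genes lay within 1.5-fold. Among the 10739 genes with 100 or more counts in both libraries, 3 were higher and 1 lower. In the simulation, which holds counting error only, the same rule called 26 of 12488 unchanged genes, so some of these calls may be counting error. SERPINE2, an inhibitor of serine proteases, had 87 counts in hypoxia and 16 in normoxia (ratio 5.10, 2.97 to 9.31). C2CD4A had 180 and 43 (3.93, 2.80 to 5.61) and the stromelysin MMP3 had 89 and 23 (3.63, 2.27 to 6.02). IGFBP3, which binds insulin-like growth factors, had 2222 and 1010 (2.06, 1.91 to 2.22). On the lower side, the cystathionine synthase CBS had 128 counts in hypoxia and 250 in normoxia, 2.08-fold lower. CCN1, a matricellular protein, had 4277 and 6387 (1.59-fold lower), the smooth muscle actin ACTA2 518 and 816 (1.68-fold lower) and the keratin KRT7 was at -0.42 (-0.45 to -0.40). Values of CBS, CYP2D6, CT45A5, PPP2R3B-2 and DHRSX-2, which passed the size rule, are uncertain because these genes share sequence with near-identical copies. With a filter at a CPM of 5 the size rule called 7 genes higher and 1 lower.

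**Figure D2:**
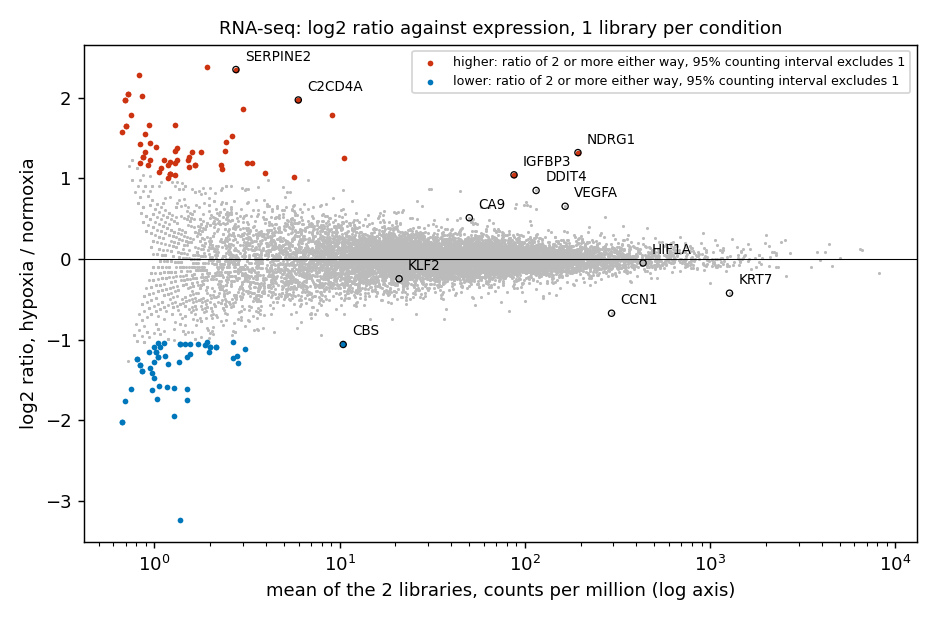
Each point is 1 gene that passed the filter, placed by the mean CPM of the RNA-seq libraries (x axis, log scale) and its log2 ratio of hypoxia to normoxia (y axis), with genes past the size rule in red (higher) and blue (lower). Genes past the size rule gather at low CPM, while NDRG1 (1.32) and IGFBP3 (1.04) stand apart at high CPM. Y-linked genes and XIST are not drawn.

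KLF2 and the gene of VEGFR2 (KDR), the factors named in the title, were measured in the same libraries. KLF2 (Entrez 10365, GRCh38.p14 chromosome 19, 16324826 to 16328685), a zinc finger transcription factor, had 362 counts in hypoxia and 402 in normoxia, a log2 ratio of -0.24 (-0.45 to -0.04). The 13 reference genes, with a median of -0.02 (-0.05 to 0.01), ran from -0.26 (GUSB, -0.39 to -0.14) to 0.19 (YWHAZ, 0.16 to 0.23). KLF2 thus lay within the range of the reference genes. KDR had 5 counts in hypoxia and 6 in normoxia, a log2 ratio of -0.36 (-2.41 to 1.62), so a difference was not detectable at this depth. EGFR was at 0.30 (0.24 to 0.36). Over the 7 measured genes of the KLF2 and VEGFR list the median was -0.06 (-0.11 to 0.02), with NRP1 highest at 0.32 (0.26 to 0.38) and THBD lowest at -0.61 (-1.09 to -0.14). The interval of 3 members lay wholly below 0 and that of 1 wholly above.

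The second comparison asked which miRNAs differed between hypoxia and normoxia. miR-671-3p (TCCGGTTCTCAGGGCTCCACC) had 80 reads in hypoxia and 28 in normoxia. After TMM scaling its log2 ratio was 3.39 (2.75 to 4.07), a ratio of 10.5 (6.75 to 16.8). It made up 1.22% of miRNA reads in hypoxia (0.966 to 1.51, exact Clopper-Pearson) and 0.0872% in normoxia (0.0579 to 0.126). Scaled to the total that the authors' TPM imply, its log2 ratio was 1.22. Its gene, MIR671, lies on chromosome 7 (151238421 to 151238538, GRCh38.p14) within the span of CHPF2 (151232483 to 151238822), whose mRNA was at -0.16 (-0.25 to -0.07).

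The size of every miRNA difference depends on the scaling. miRNA reads were 0.361% of the implied total in normoxia and 0.0601% in hypoxia, 6.01-fold less, and moving from TMM to that total shifts every log2 ratio by -2.18. Moving from TMM to total counts shifts it by 0.41. Of the 118 miRNAs with a ratio, 67 had 0 reads in 1 library and were set at the floor of 3 counts. With these limits included the median log2 ratio was -0.79 with TMM, a value that is itself such a limit, and over the 51 read in both libraries it was -0.00040. TMM takes its factor from these 51 miRNAs, so a median near 0 is set by the scaling and is not a measured lack of shift. By the size rule 30 miRNAs were higher and 52 lower with TMM (36.6% of calls higher), while 15 were higher and 83 lower when scaled to the implied total (15.3% higher). With the authors' TPM and a pseudocount of 1 the split was 15 and 78 (16.1% higher), and with a pseudocount of 10 it was 0 and 33 (0% higher). Total counts moved it the other way, to 32 higher and 41 lower (43.8% higher), with a median of -0.37 over the 118. Among the miRNAs read in both libraries, 16 were higher and 15 lower with TMM. This near-balance follows from the scaling, which centres these same miRNAs, and does not show where the excess of lower calls comes from. With TMM, 37 of the lower calls had 0 reads in hypoxia and 14 of the higher calls had 0 in normoxia.

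Most let-7 family members, tumour-suppressive miRNAs, were lower in hypoxia. With TMM, 6 of 9 were called lower, against 52 of all 118 miRNAs with a ratio. The let-7 median lay at percentile 3.66 of lists matched on expression, inside the central 95%. The median of -1.40 falls on miR-98-5p, which had 0 reads in hypoxia and 29 in normoxia and was set at the floor, so it is a limit and not an estimate. Over the 7 members read in both libraries the median was -1.67. let-7a-5p had 141 reads in hypoxia and 2408 in normoxia, 4.65-fold lower, and let-7c-5p had 1 and 268 (log2 -6.19, -11.50 to -3.70). let-7e-5p (126 and 130 reads) was at 1.83 and let-7g-5p (44 and 65) at 1.31 with TMM, and both lay below 0 when scaled to the implied total, at -0.34 and -0.86. The oncogenic miR-21-5p had 37 and 338 reads, 2.49-fold lower (log2 -1.31, -1.85 to -0.82). miR-375-3p had 0 reads in hypoxia and 1076 in normoxia, at least 97.7-fold lower, and miR-744-5p 0 and 196, at least 17.8-fold lower, both with TMM and against the floor of 3 counts. Counting error in normoxia adds to this floor: the upper 95% bounds of their ratios were 0.0126 and 0.0698. miR-25-3p had 11 and 957 reads, 23.7-fold lower, although its other strand miR-25-5p had 20 and 0.

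Of the 141 miRNAs, 51 were detected in both libraries, 65 in normoxia alone and 25 in hypoxia alone. In the last group miR-328-3p had 87 reads (at least 107-fold higher with TMM against the floor of 3 counts, lower 95% bound of the ratio 84.8) and miR-9-3p 71 (at least 86.9-fold, lower bound 68.9). miR-139-5p had 58 reads (at least 71.0-fold, lower bound 55.9) and miR-128-3p 52 (at least 63.7-fold, lower bound 49.95). In the miR-30 family, where all 6 members had 0 reads in 1 library, 5 were lower, such as miR-30e-3p with 0 and 180 reads, while miR-30d-5p had 39 and 0. The median of this family lay at percentile 11.5 of matched lists. Abundant miRNAs of liver, muscle and blood were also seen: miR-122-5p had 169 and 142 reads (log2 2.13, 1.80 to 2.46) and miR-1-3p 78 and 86 (1.74, 1.27 to 2.19), both higher with TMM and at -0.05 and -0.44 when scaled to the implied total, while the muscle miRNA miR-206 had 1 and 76 (-4.37, -9.69 to -1.85). Of 9 miRNAs linked to angiogenesis, 3 were called lower and 0 higher with TMM, and 4 were at the floor. Of all 118 miRNAs with a ratio 52 were called lower, and the median of these 9 lay at percentile 38.3 of matched lists. The list thus did not stand apart from other miRNAs. Over the 5 read in both libraries the median was -0.45. The endothelial miR-126-3p had 29 and 140 reads (-0.39, -1.02 to 0.19). Of 14 listed miRNAs linked to hypoxia, 2 were among the 141 and 1 had a ratio, miR-26a-5p at -0.24 (-0.73 to 0.23) with TMM. Neither strand of miR-210 was among the 141, so its response to hypoxia could not be read here. With 6576 reads in the hypoxia library, these ratios rest on few reads.

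**Figure D3:**
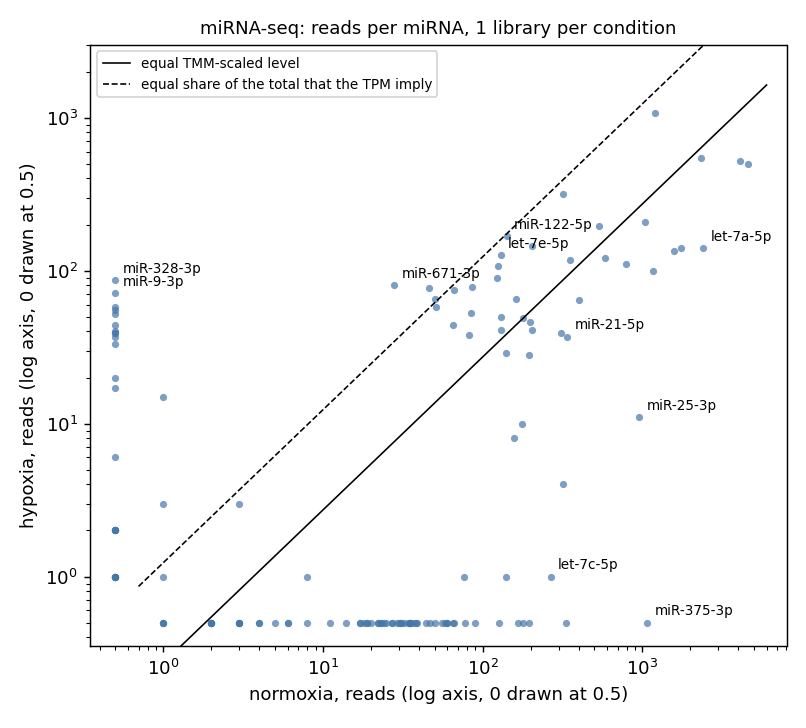
Each point is 1 miRNA, placed by its reads in normoxia (x axis) and in hypoxia (y axis), both on log scales with 0 drawn at 0.5. Points on the solid line are equal after TMM scaling and points on the dashed line are equal as shares of the total that the TPM imply. miR-671-3p (28 and 80 reads) lies above both lines, and miR-375-3p (1076 and 0) below both.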

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

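The length correction, the summing of gene copies, the scaling to the implied total and the restriction to miRNAs read in both libraries were chosen after seeing the data, and all other alternatives were planned. DESeq2 size factors and upper quartile scaling kept the 210 RNA-seq results followed, and total counts moved 1. A list median or gene was kept when it stayed within its counting interval. A number of calls was kept when it stayed within 1.5-fold of the main number. FPKM with a pseudocount of 1 moved 22, and removing the length trend moved 9 and reversed 1. The count of higher genes (60) was 6 with FPKM and a pseudocount of 1, 30 with 0.1, 100 with no filter, 7 at a CPM of 5 and 19 with the interval beyond 1.5. The count of lower genes (56) was 1, 20, 104, 1 and 10 in the same order. A filter or pseudocount acts on genes with few reads, where most calls lie. The HIF target median was 0.29 with FPKM and a pseudocount of 1. With the length trend removed, the oxidative phosphorylation median was -0.022 and the ribosomal protein median 0.0029, above 0. The leukocyte median turned to 0.056 at a CPM of 5, which keeps fewer of its 4 genes. The KLF2 log2 ratio stayed within its main interval (-0.45 to -0.04) under every scaling, FPKM, filter and length alternative. That interval ends close to 0, and whether it still excluded 0 under each alternative was not followed.

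The miRNA filters changed nothing. Total counts moved 24 of 54 miRNA values and reversed 0, and the let-7 median was -0.99. Over miRNAs read in both libraries, where no value is set at a floor, 16 were higher, 15 lower and the let-7 median was -1.67. TMM centres these miRNAs near 0, so the balance of 16 and 15 follows from the scaling. The values below are for TPM with a pseudocount of 1, TPM with a pseudocount of 10 and the implied total, in that order. Higher miRNAs (30) numbered 15, 0 and 15. Lower miRNAs (52) numbered 33 with a pseudocount of 10 and 83 with the implied total. The let-7 median was -3.48, -1.99 and -3.57. miR-671-3p was at 1.00, 0.40 and 1.22, above 0 in each. These turned below 0: let-7e-5p at -0.32, -0.19 and -0.34; let-7g-5p at -0.73, -0.30 and -0.86; miR-27a-5p at -0.75, -0.50 and -0.79; miR-122-5p at -0.045, -0.029 and -0.048; miR-1-3p at -0.39, -0.20 and -0.44; and the liver, blood and muscle list at -0.93, -0.51 and -1.03. The larger denominator moves all miRNAs by one factor, and a pseudocount of 10 exceeds the TPM of most miRNAs. No paired analysis was possible because each group has 1 library. The seed-site search was not run.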

Other observations

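The tests of template number, sequencing depth, processing genes and YAP and SRF targets were chosen only after the results were seen. The tests of length, gene copies and host genes were written down before their results.

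A group not described above was lower in hypoxia. CCN1 and ACTA2 are targets of the YAP and SRF transcription factors, which answer to cell tension and the actin skeleton. A list of such targets was written from memory after these genes had been seen, and it included genes such as CCN2 (log2 ratio -0.65, -0.76 to -0.54), ANKRD1 (-0.72, -1.10 to -0.35) and MYL9 (-0.28, -0.34 to -0.22). The 25 targets that no fixed list or named gene covers had a median of -0.13, with 17 below 0 and 8 above 0. It lay at percentile 0 of 10000 lists matched on expression, and at percentile 0.01 when length was matched too. The list was chosen because its leading members were low, so lower YAP or SRF output in the hypoxia library is a hypothesis that may be worth a replicated test. PTPN14 (0.23, 0.14 to 0.33) and MYOF (0.11, 0.08 to 0.14) went the other way.

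The first pattern weighed is that whole lists shift. Log2 ratios rose with gene length across 12725 genes (Spearman rho 0.21 across genes, which are not independent replicates), from a median of -0.06 in the shortest 10% of genes to 0.07 in the longest, as a difference in RNA quality or library preparation could give. Against lists matched on both expression and length, HIF targets stayed at percentile 100, and S phase and immediate early genes at percentile 0, so a length trend does not account for these lists. Oxidative phosphorylation genes moved to 1.43, which leaves the trend open for them. A response to hypoxia and a difference between single cultures cannot be separated with 1 library per group.

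The second pattern is the small and one-sided miRNA profile in hypoxia. If reads are taken as independent molecules, fewer miRNA reads alone do not account for it. In hypoxia 12 miRNAs had 20 or more reads and 0 in the normoxia library, which had more miRNA reads, with intervals above 1. These intervals cannot exclude the sampling of few molecules. Lower transcripts of miRNA processing genes are not seen, since their median log2 ratio was 0.016 (-0.02 to 0.12). Amplification of few template molecules stays open: in normoxia 7 miRNAs had 5 to 14 reads and 32 had 20 to 59, a ratio of 0.219, and in hypoxia 4 and 23, a ratio of 0.174, against 0.903 and 0.888 for genes in the RNA-seq libraries. The gap was noticed before it was measured, so it cannot count in favour of that explanation, and a few templates may also lie behind the 28 and 80 reads of miR-671-3p.

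The third pattern is the calls on second copies of pseudoautosomal genes, PPP2R3B-2 (1.79, 1.41 to 2.18) and DHRSX-2 (-3.23, -4.92 to -1.90). Reads shared between identical copies could cause this. Summed copies would decide it, but of these 2 genes 0 have a row for the other copy among the values used, so it stays open.

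Whether miRNA ratios follow their host genes was tested over 13 pairs fixed before the data were examined. The hypothesis predicted a positive relation. Spearman's rho was -0.53, but in 6 of the 13 pairs the miRNA had 0 reads in hypoxia and its ratio is a limit set by the floor, so this rho does not rank measured ratios and decides nothing. Over the 7 pairs read in both libraries, a subset taken after the result was seen, rho was -0.58 (exact permutation p = 0.187) and Pearson's r -0.30 (exact permutation p = 0.434), or 0.375 and 0.434 after Benjamini-Hochberg adjustment over 2 relations. Pairs are not replicates, some share a host, and the question stays open.

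Pathway annotation in the RNA-seq table was scanned after the lists, over 311 pathways with 10 or more members. 5 pathways lay above and 3 below the central 99% of lists matched on expression and length. If the genes of a pathway vary independently, 1.56 are expected in each tail. Genes that vary together would raise that number, so 5 and 3 are not shown to exceed it. In the upper tail, Staphylococcus aureus infection (median 0.17 over 31 genes), systemic lupus erythematosus (0.15 over 62) and starch and sucrose metabolism (0.14 over 18) each had 0 of 10000 matched lists as high, and hematopoietic cell lineage (0.13 over 34) had 2 and rheumatoid arthritis (0.05 over 51) 15. In the lower tail were hepatocellular carcinoma (-0.03 over 136, percentile 0.28), thermogenesis (-0.05 over 187, percentile 0.35) and steroid hormone biosynthesis (-0.18 over 19, percentile 0.48), whose median was the farthest from 0 of those named. The pathways nearest to the fixed lists lay inside the central 99%: HIF-1 signaling at percentile 84.7, glycolysis and gluconeogenesis at 97.4, DNA replication at 10.2, cell cycle at 17.2 and oxidative phosphorylation at 5.20. The scanned pathways share genes with each other and with the fixed lists: H2BC7 of the histone list was the highest member of systemic lupus erythematosus. Pathway names describe annotation, not these cells.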
